A study of Mus musculus with 2 samples.

How the data were processed

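Small RNA libraries under 30 nucleotides were made from total RNA of embryonic day 14.5 mouse hindbrain, strain B6NCrl, 1 library for each of 2 replicates, per the labels. Each sample is described as a single hindbrain in 1 label and as pooled male and female in another, and both samples carry the same donor label. Whether each library holds RNA of 1 embryo, and whether they come from separate animals, is therefore open, and n, SD, the coefficient of variation and p-values measure only the spread between these samples.

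The deposited tables hold raw read counts per microRNA locus, not normalized, with a column for both strands and a column for each strand. The lists of files deposited with the tables name the mm10 build and annotation release M4, and the aligner and counting program are not given in the sources used here. For all 1973 loci the count on both strands equalled the sum of the strand columns. The strand column with the larger total, 98.0% of counts on loci in replicate 1 and 97.8% in replicate 2, was taken as the gene strand. The 4 rows of unassigned reads were left out of library sizes and tests. They held 13.8% unmapped, 33.9% multimapping and 2.99% reads outside the listed loci in replicate 1, of 11804816 reads, and 15.9%, 34.3% and 3.31% in replicate 2, of 14348369 reads, with 0 ambiguous reads. Multimapping reads were not assigned to loci, so the counts of loci with near-identical copies leave out any such reads. CPM values of different loci also carry the capture bias of small RNA libraries, which was not measured here.

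Symbols, coordinates and host genes came from GENCODE M21 on the same build (GRCm38), matched on the stable part of the identifier for 1894 of the 1973 loci. The 79 unmatched loci held 7 counts in all. A locus was treated as having a copy when another hairpin shared a run of 20 bases, which held for 919 loci. All 32 overlapping opposite-strand pairs of loci have a row for only 1 of the pair, so reads of the other locus stand in the opposite-strand column.

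CPM was the gene-strand count per 1000000 counts on loci. A locus was detected with at least 10 counts in each library. Shares have Clopper-Pearson 95% intervals, and the floor is 3 counts. Counts were scaled by TMM in edgeR (factors 0.985 and 1.01), and the log2 ratio of replicate 2 over replicate 1 added 0.5 to each count. Each of 498 loci with a summed count of at least 10 was tested with an exact two-sided binomial test against the share set by the effective library sizes, adjusted by Benjamini-Hochberg at 0.05. A quasi-likelihood test has no residual degrees of freedom here. An exact test with edgeR's common dispersion was an alternative. That dispersion was estimated from the same 2 libraries, so real differences enlarge it. List medians were placed among 10000 random lists, for ratios with each member replaced by 1 of the 50 loci nearest in mean level.

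The 14 lists, the tests of the main results and the naming rule were fixed before the data were examined, while tests of explanations were chosen later where the closing section says so. The rule named the 20 loci with the highest mean CPM, up to 4 leading members of each list, and the 5 highest and 5 lowest log2 ratios among loci with at least 100 counts in each library that passed the binomial test. The multi-copy loci Mir124a and Mir9-3 were chosen after their values were seen, as were other loci outside the rule.

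The scripts were tested on simulated data for the comparison of replicate 2 with replicate 1 over 498 loci. With Poisson counts and no change, the binomial test called 0 loci. With an added coefficient of variation of 10% and no change, it called 178 of 498 loci, the estimated coefficient was 9.98%, and the test with the common dispersion called 0. With Poisson counts and 50 loci at each fold, the binomial test recovered 46% of loci changed 1.2-fold, 58% at 1.5-fold, 68% at 2-fold and 80% at 4-fold. The test with the common dispersion recovered 0% at each fold because the changed loci enlarged the dispersion. The estimated coefficient of variation there was 33.5%, against 10.8% in the data. The power of the test with the common dispersion in these data was therefore not measured. A list of 15 shifted by 0.25 log2 lay at percentile 100 and an unshifted list at 71.6.

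Alternatives covered the count minimum, the denominator, the strand, the scaling (library totals, DESeq2 size factors, upper quartile), the low-count filter, the pseudocount, summed copies, the random lists and leaving out each replicate. Crediting opposite-strand counts to the overlapping partner locus was added after the data were seen. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.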

Results

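Small RNA was sequenced from mouse hindbrain, the part of the embryonic brain that forms the cerebellum, pons and medulla, at embryonic day 14.5. The tissue came from strain B6NCrl, and the libraries held RNA under 30 nucleotides, the size class of mature microRNAs. The series holds 1 group of 2 replicate libraries, collected on 24 July 2014 (replicate 1) and 30 July 2014 (replicate 2), 6 days apart. Replicate 1 had 5826676 counts on microRNA loci and replicate 2 had 6667238. With 1 group, no conditions could be compared, so levels, fixed microRNA lists and the difference between the replicates are described. Levels are CPM, the count of a locus per 1000000 counts on microRNA loci, or shares of those counts, as mean ± SD over 2 libraries. All intervals and floors cover counting error only, because no molecular identifiers were counted.

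Ranks and shares cover reads assigned to 1 locus, so microRNAs whose reads map to several positions can be ranked too low. The most abundant locus was Mir99a, which shares its host transcript with let-7c, with 16.05% ± 0.857 of the assigned microRNA counts (SD, n = 2). Mir10a and Mir10b, encoded inside the Hox clusters that pattern the hindbrain and spinal cord, followed with 9.64% ± 1.71 and 6.32% ± 1.04 (SD, n = 2). Mirlet7g and Mirlet7i, members of the let-7 family that rises with differentiation, held 4.74% ± 0.479 and 3.55% ± 0.380 (SD, n = 2). Mir100, a paralog of Mir99a, held 3.42% ± 0.0445, and Mir126a, the endothelial microRNA of the Egfl7 gene, held 3.42% ± 0.347 (SD, n = 2). The imprinted locus Mir487b held 3.07% ± 0.278, Mir335 in an intron of the imprinted gene Mest held 2.74% ± 0.0830, and Mir130a held 2.51% ± 0.0612 (SD, n = 2).

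Together these 10 loci held 55.5% ± 0.476 of the microRNA counts (SD, n = 2). The share was 55.8% in replicate 1 (95% Clopper-Pearson interval 55.76 to 55.84) and 55.1% in replicate 2 (55.09 to 55.17). The next 10 loci were Mir30e, Mir99b, Mir17, Mir149, Mir181c, Mir26b, Mir137, Mir30a, Mir135b and Mir125a, and the top 20 held 68.8%. Among the 20, 11 lay in introns, 5 overlapped exons and 4 were intergenic. Mir99a lies on chromosome 16 at 77598936 to 77599000 (GRCm38) in an intron of Mir99ahg. Mir10a lies on chromosome 11 at 96317165 to 96317274 in the Hoxb cluster, outside annotated genes, and Mir10b on chromosome 2 at 74726070 to 74726137 in an intron of Hoxd3. A total of 401 loci had at least 10 counts in each library, and 1230 had 0 counts in both, which allows up to 0.515 CPM in replicate 1 and 0.450 CPM in replicate 2.

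Among the 14 lists, the list named neural progenitor held the largest share, 29.5% ± 0.973 (SD, n = 2). Its leading members were Mir99a (16.05%), Mir100 (3.42%), Mir130a (2.51%) and Mir99b (2.04% ± 0.0259). The share thus rested mostly on Mir99a, and whether these loci mark progenitors in this tissue was not tested. The Hox cluster list held 16.2% ± 2.82, the let-7 list 10.03% ± 1.08 and the list of the imprinted Dlk1-Dio3 cluster 9.21% ± 0.792 (SD, n = 2). Mir487b led the Dlk1-Dio3 list, followed by Mir411 with 7148 ± 1281 CPM, Mir127 with 7134 ± 618 CPM and Mir369 with 6426 ± 982 CPM (SD, n = 2). The list of the miR-17 paralogous clusters, which are active in proliferating cells, held 3.87% ± 0.368, led by Mir17 with 14345 ± 1749 CPM, Mir106b, Mir93 and Mir20a. The neuronal list held 3.50% ± 0.319, led by Mir149 with 14266 ± 1557 CPM, Mir137 with 10171 ± 671 CPM, Mir153 with 2259 ± 416 CPM and Mir128-1 with 1781 ± 169 CPM (SD, n = 2). The 14 lists together held 78.3% ± 0.305 of the microRNA counts.

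Among lists for other cell types, the vascular and mesenchymal list held the largest share, 4.59% ± 0.393 (SD, n = 2). Mir126a made up most of that list, and Mir143 of smooth muscle had 6635 ± 229 CPM, Mir140 of cartilage 4330 ± 289 CPM and Mir214 of mesenchyme 224 ± 27.9 CPM. The sensory and choroid list held 0.656% ± 0.0428, with Mir204 of choroid plexus and pigment epithelium at 2456 ± 428 CPM and Mir182 of sensory epithelia at 2071 ± 160 CPM. The oligodendrocyte list held 0.319% ± 0.0215, with Mir219a-2 at 2618 ± 252 CPM and Mir338 at 417 ± 39.6 CPM. The liver and pancreas list held 0.134% ± 0.00875, led by Mir375 at 623 ± 83.3 CPM, and the pluripotency list held 0.1001% ± 0.00534, led by Mir302a at 368 ± 16.9 CPM. The blood and immune list held 0.0764% ± 0.00893, with the red cell microRNA Mir451a at 274 ± 56.8 CPM and the myeloid microRNA Mir223 at 201 ± 10.04 CPM. The epithelial list held 0.0760% ± 0.000942, led by Mir203 at 648 ± 11.6 CPM. The muscle list held 0.00283% ± 0.000217, and its leading member Mir206 had 15.6 ± 0.896 CPM.

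**Figure D1:**
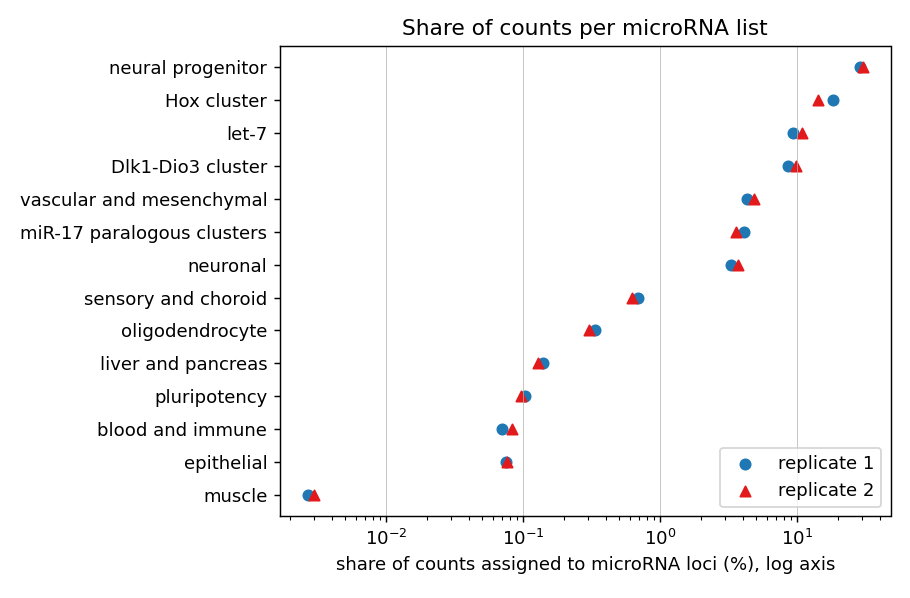
Share of the counts on microRNA loci held by each of the 14 lists, in percent on a log axis, with a circle for replicate 1 and a triangle for replicate 2. The neural progenitor list lies highest at 28.8% and 30.2%, and the muscle list lowest at 0.00268% and 0.00298%.

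The median level of the detected members of each list was set against 10000 random lists of equal size drawn from detected loci. That of the neural progenitor list lay at the 100th percentile, that of the let-7 list at 99.5 and that of the Dlk1-Dio3 list at 99.2. The Hox list lay at 96.8, the sensory and choroid list at 93.7, the neuronal list at 89.8 and the miR-17 list at 87.5. The oligodendrocyte list lay at 74.3, the vascular list at 67.2, the liver and pancreas list at 41.4 and the blood list at 40.7. The pluripotency list lay at 25.9, the epithelial list at 12.9 and the muscle list at 1.55. The muscle position, from 4 detected members of 10, depended on the setting. With all 10 members, among lists drawn from all loci of the tables, most of which had no counts, it was 90.6.

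Mir124a, made from several near-identical hairpins, had low counts, while other loci with a copy, such as Mir487b and Mir411, were abundant. The 3 Mir124a loci, whose product is the main neuronal microRNA of the brain, together had 11.9 ± 0.338 CPM (SD, n = 2). The 2 listed Mir9 loci, of the neural progenitor microRNA miR-9, together had 518 ± 15.3 CPM (SD, n = 2), nearly all of it from Mir9-3 with 516 ± 15.3 CPM. Reads that mapped to several positions, 33.9% of all reads in replicate 1 and 34.3% in replicate 2, were not assigned to any locus. Levels of loci with a near-identical copy, 13 of the 23 neuronal, 10 of the 20 neural progenitor and 5 of the 10 let-7 members, are therefore uncertain, and with them the shares of these lists. The same holds for the muscle list with 4 of 10 members, the lowest in share and level, for the oligodendrocyte list with 2 of 3, the pluripotency list with 4 of 12, the Hox list with 2 of 6, the miR-17 list with 4 of 15, the vascular list with 3 of 11, the liver and pancreas list with 2 of 8, the Dlk1-Dio3 list with 6 of 49 and the blood list with 1 of 8. The epithelial and the sensory and choroid lists had 0 such members, but their shares too divide by a total that leaves out multimapping reads. Among let-7 members, Mirlet7a-1 had 227 ± 35.2 CPM and Mirlet7a-2 192.3 ± 25.2 CPM (SD, n = 2), both named after their values were seen. Equally uncertain are the levels of Mir487b, Mir411, Mir128-1, Mir219a-2 and Mir302a.

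Mir144 and Mir449a had the highest and the lowest log2 ratio among loci with at least 100 counts in each library that passed the test of counting error. Mir144, a red cell microRNA on chromosome 11 at 78073005 to 78073070, was 2.14-fold higher in replicate 2 (log2 ratio 1.10, exact 95% interval 0.83 to 1.37). Mir449a, a microRNA of multiciliated cells in an intron of Cdc20b on chromosome 13 at 113037534 to 113037624, was 1.87-fold higher in replicate 1 (log2 ratio -0.90, -0.93 to -0.88). Mir1298, in an intron of the serotonin receptor gene Htr2c on chromosome X at 147064905 to 147065002, was 1.69-fold higher in replicate 1 (log2 ratio -0.76, -0.78 to -0.73). Both libraries came from the same group, so these differences have no replicate check, and collection day coincides with replicate.

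Across the 498 loci with a summed count of at least 10, Pearson's r of log2(CPM + 1) was 0.997 and Spearman's rho was 0.987, across loci, which are not independent replicates. Among 282 loci with at least 100 counts in each library, the SD of the log2 ratio was 0.22 and 7 differed by more than 1.5-fold. The common dispersion of edgeR corresponded to a biological coefficient of variation of 10.8% between these libraries, which the labels do not show to come from separate animals. The chi-square statistic of the counts was 146.1 per degree of freedom, so the files differed by more than sampling noise and were kept as separate libraries.

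**Figure D2:**
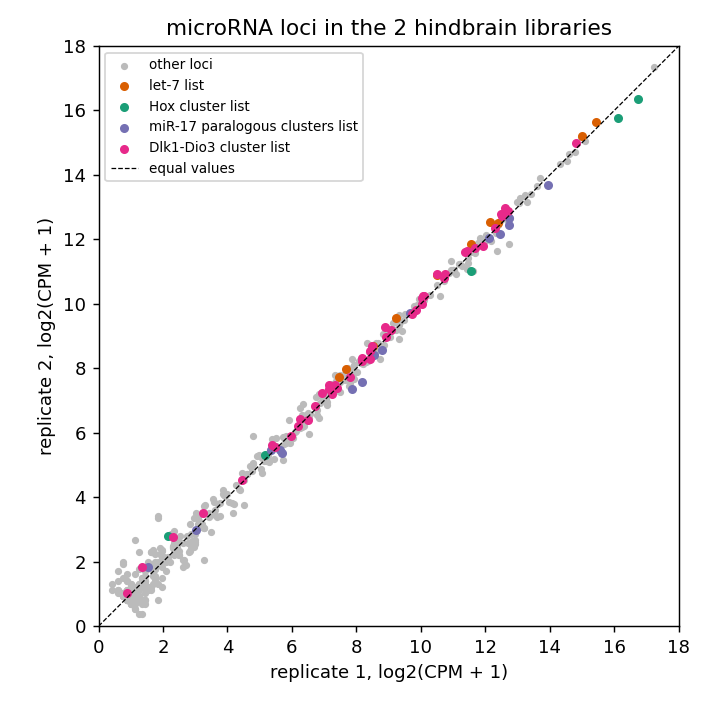
Level of each of the 498 compared loci in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both as log2(CPM + 1), with 4 lists in colour and the dashed line marking equal values. Pearson's r across these loci is 0.997.

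An exact two-sided binomial test per locus, with Benjamini-Hochberg adjustment at 0.05, called 162 of the 498 loci beyond counting error, 87 higher and 75 lower in replicate 2. With library totals in place of TMM scaling the split was 114 higher and 59 lower. It was 90 and 67 without a filter, and 92 and 76 with counts of both strands. More loci were lower with DESeq2 size factors (80 higher, 88 lower), upper quartile (82, 87) and a summed count of at least 100 (78, 84). The direction of the excess therefore depended on the setting. The test compares these 2 libraries, not conditions. When edgeR's common dispersion was allowed for, 7 loci were called, of which 4 were higher in replicate 2 (Mir144, Mir184, Mir5126 and Gm23134) and 3 were lower (Mir449a, Mir449b and Mir1298). Apart from Mir144, Mir449a and Mir1298, these were named after their values were seen and had at most 65 counts in a library.

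Beyond counting error, all 10 let-7 members with a row of their own were higher in replicate 2, while the Hox members Mir10a, Mir10b and Mir615 were lower. Mirlet7e and Mirlet7f-1, counted only in the opposite-strand column, are not among these 10, and no test is reported for them. Before TMM scaling, Mirlet7e had 4078 CPM in replicate 1 and 4263 CPM in replicate 2, and Mirlet7f-1 had 56.6 and 77.4 CPM. Log2 ratios with library totals lay 0.04 above those with TMM scaling. The values before scaling therefore do not show that Mirlet7e was higher in replicate 2 as the 10 were. With opposite-strand counts credited to the partner locus, the let-7 median was 0.24 at percentile 100. With edgeR's common dispersion allowed for, 0 of the 76 measured members of the let-7, Hox, miR-17 and Dlk1-Dio3 lists were called (3 at an unadjusted p under 0.05). The 10 let-7 members passed the binomial test, with 10 called when adjusted over the list alone, and their median log2 ratio was 0.24. Mirlet7d had a log2 ratio of 0.33, Mirlet7i 0.18, Mirlet7g 0.16 and Mirlet7b 0.05. Of 5 measured Hox cluster members 3 were lower and 2 did not pass (3 called when adjusted over the list alone), with a median of -0.38. Mir615 had a log2 ratio of -0.58, Mir10a -0.41 and Mir10b -0.38, while Mir196b and Mir196a-2, of the posterior Hox genes, lay above 0 with 0.09 (-0.18 to 0.36) and 0.75 (-0.05 to 1.62, from 20 and 40 counts) and did not pass. Of 15 members of the miR-17 paralogous clusters 10 were lower, 0 were higher and 5 did not pass (10 called when adjusted over the list alone), with a median of -0.20. Mir20a had a log2 ratio of -0.31, Mir93 -0.30, Mir17 -0.29 and Mir106b -0.11. Of 46 measured Dlk1-Dio3 members 17 were higher, 3 were lower and 26 did not pass (21 called when adjusted over the list alone), with a median of 0.10. Mir411 had a log2 ratio of 0.33, Mir369 0.27, Mir487b 0.14 and Mir127 0.13.

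Among 10000 random lists matched on mean expression, the let-7 median lay at percentile 99.99, the Dlk1-Dio3 median at 99.93, the Hox median at 0.900 and the miR-17 median at 0.0700. These percentiles describe the 2 libraries. Members of the Dlk1-Dio3 and miR-17 lists share transcripts and let-7 members share sequence, so they are not independent draws as the random lists are. The Hox median, over 5 measured members, was the value of Mir10b, and the independence of those members was not tested.

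**Figure D3:**
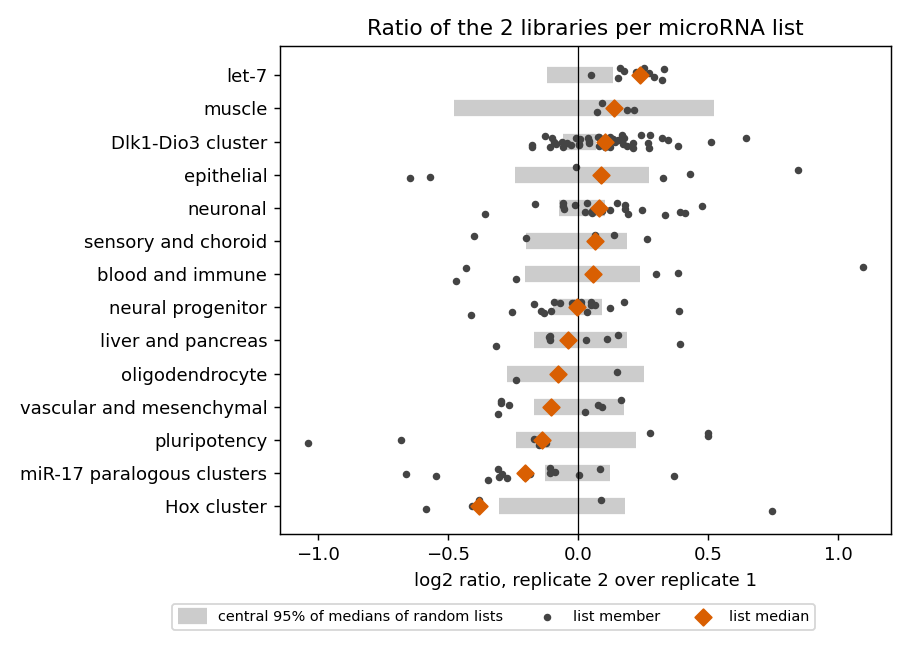
Log2 ratio of replicate 2 over replicate 1 for each measured list member (points), the list median (diamond) and the central 95% of medians of 10000 random lists matched on mean expression (grey bar). The let-7 median of 0.24 and the Dlk1-Dio3 median of 0.10 lie above their bars, and the Hox median of -0.38 and the miR-17 median of -0.20 lie below theirs.

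The medians of the other 10 lists lay within the central 95% of matched random lists. Calls of their members given below are those of the binomial test. With the common dispersion allowed for, 0 members were called in each of these lists except blood and immune, with 1 (Mir144). The neuronal list had 9 members higher, 1 lower and 13 not passing (10 called when adjusted over the list alone), with a median log2 ratio of 0.08 at percentile 90.3 and 0.33 for Mir153. The neural progenitor list had 3 higher, 8 lower and 9 not passing (11 when adjusted over the list alone), with a median of -0.00 at percentile 39.9 that turned to 0.04 with library totals and 0.01 with members of at least 100 summed counts, and a ratio of summed counts of 0.02. The vascular and mesenchymal list had 3 higher, 3 lower and 3 not passing (6 when adjusted over the list alone), with a median of -0.10 at percentile 13.8, while the ratio of its summed counts, led by Mir126a, was 0.13 and the median over members with at least 100 summed counts was 0.03, both of the other sign. The blood and immune list had 3 higher, 1 lower and 3 not passing (5 when adjusted over the list alone), with a median of 0.06 at percentile 66.2. Its median was 0.18 with members of at least 100 summed counts (percentile 94.3) and also with opposite-strand counts credited to the partner locus (percentile 95.6), and Mir451a had 0.38. Mir486, also of red cells and named after its values were seen, had -0.47 and did not pass. The sensory and choroid list had 2 higher, 2 lower and 1 not passing (4 when adjusted over the list alone), with a median of 0.07 at percentile 71.7 and a ratio of summed counts of -0.18, led by Mir204 with -0.40. The median over its members with at least 100 summed counts was -0.07 at percentile 15.5, so its direction depended on the setting.

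The oligodendrocyte list had 1 member higher, 1 lower and 1 not passing (2 when adjusted over the list alone), with a median of -0.07 at percentile 23.8, which turned to 0.04 with opposite-strand counts credited to the partner locus. The pluripotency list had 0 higher, 3 lower and 6 not passing (5 when adjusted over the list alone), with a median of -0.14 at percentile 19.015. The liver and pancreas list had 0 higher, 2 lower and 6 not passing (2 when adjusted over the list alone), with a median of -0.04 at percentile 31.6 that turned to 0.01 with library totals and was -0.11 (percentile 12.1) with members of at least 100 summed counts, and Mir375 had -0.32. The epithelial list had 0 higher, 1 lower, which was Mir205 with -0.64, and 6 not passing (1 when adjusted over the list alone), with a median of 0.09 at percentile 69.5 and a ratio of summed counts of -0.02, of the other sign. None of the 4 measured muscle members passed the binomial test (0 when adjusted over the list alone), with a median of 0.14 at percentile 68.8, or 0.07 with members of at least 100 summed counts.

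Among loci with at least 100 counts in each library that passed the binomial test, those highest in replicate 2 after Mir144 were Mir33 in an intron of the cholesterol regulator Srebf2 (log2 ratio 0.52), Mir873a (0.48), Mir3059 (0.44) and Mir1251 in an intron of Rmst (0.42). Those lowest in replicate 2 besides Mir449a and Mir1298 were Mir106a (-0.66), Mir34c of multiciliated cells (-0.65) and Mir205 (-0.64).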

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

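Of the tests in this part, the one on low abundance in the tissue was chosen after the result was seen. Reads outside the main measurement stood above the limit that a count of 0 allows. Multimapping reads numbered 4000369 in replicate 1 and 4917403 in replicate 2. Opposite-strand counts on loci numbered 118521 and 150352. Reads outside the listed loci numbered 353116 and 475318.

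Mir124a had low counts in a brain tissue (11.9 CPM summed over 3 loci). A candidate explanation is that reads with more than 1 position were left out of the locus counts. The comparison used 22 clusters of neighbouring loci that hold members with and without a near-identical copy. Those with a copy were lower in 17 clusters, higher in 4 and equal in 1. The median log2 difference was -3.86 and the mean was -3.05 (two-sided permutation test of the mean by sign flips, p = 0.00165). The clusters include that of Mir124a-1 itself (-1.18). Some hold copies of the same microRNA, such as Mirlet7c-1 and Mirlet7c-2, so they are not independent, as the test takes them to be. Leaving out reads with more than 1 position could only remove reads from loci with a copy, and neighbours are often different microRNAs. The test therefore does not show why Mir124a was low. The largest difference was that of Mirlet7c-1, with 390 CPM beside 160496 CPM for its neighbour Mir99a. Low abundance in the tissue cannot be told apart from the loss of reads with more than 1 position. There were 0.712 multimapping reads per assigned read, and the tables do not give their loci.

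Of the opposite-strand counts, 99.8% in both libraries stood in the rows of loci that overlap 11 other microRNAs, which have no row of their own and were picked out after their values were seen. Mir376a of the Dlk1-Dio3 cluster would have 6742 ± 988 CPM from these counts, ahead of Mir369 of the same list with 6426 ± 982 CPM. Mirlet7e would have 4170 ± 131 CPM, Mir409 3937 ± 329.3 CPM and Mir191 2394 ± 10.3 CPM (SD, n = 2). No biological explanation was tested for them.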

How the results depend on the processing

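The setting that credits opposite-strand counts to the partner locus was chosen after the data were seen. With a minimum of 1 count the detected loci numbered 641. With all reads as denominator the share of the 10 most abundant loci was 26.6% and that of the 14 lists 37.5%, since unassigned reads enter the total. With counts of both strands these shares were 54.3% and 76.7%, and with partner counts the share of the 10 loci was 54.3%. Partner counts also changed the order of some lists. The Dlk1-Dio3 share rose from 9.21% to 10.24%, beside 10.23% for let-7. The blood and immune share rose from 0.0764% to 0.103%, above 0.0981% for the pluripotency list. With all members of each list and random lists drawn from all loci, 13 of 14 lists lay outside the central 95% in level. This compares with 4 in the main setting of detected members and detected loci. The muscle list moved from 1.55 to 90.6, since most loci had no counts. With the common dispersion 7 loci were called in place of 162. The other scalings, filters and strands called between 157 and 173. The same number of lists, 4, lay outside the central 95% in ratio under each scaling, filter and partner setting run; medians of lists inside that range turned sign where the report gives it. Leaving out a replicate gave 55.1% to 55.8% for the 10 loci, 78.05% to 78.48% for the lists and 97.79% to 98.01% on the gene strand, without a test. No paired analysis was possible because the series has 1 group. Depth limits loci with few counts: Mir124a-1, with 44 and 53 counts, had a log2 ratio of 0.03 with an exact 95% interval of -0.57 to 0.64.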

Other observations

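The groups and the tests of explanations in this part were chosen after the data were seen. The list percentiles and the test with the common dispersion, repeated here, had been planned. The miR-30 family held 3.93% ± 0.155 of the microRNA counts (SD, n = 2), led by Mir30e and Mir30a. The 5 loci of the imprinted Mest, Gnas, Igf2 and H19 regions, which are not all imprinted microRNAs outside Dlk1-Dio3, held 3.58% ± 0.129 (SD, n = 2). Besides Mir335 of Mest, these were Mir298 with 4946 ± 283 CPM and Mir296 with 3192 ± 152 CPM near Gnas, Mir483 of the Igf2 region with 203.5 ± 26.5 CPM and Mir675 of H19 with 5.05 ± 0.141 CPM. The X-linked miR-322 cluster held 0.670% ± 0.0342, led by Mir322, and the miR-183 cluster of sensory cells 0.410% in both libraries.

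Mir449a, Mir34b, Mir34c and the Htr2c-intron loci Mir1298, Mir1264 and Mir448 were lower in replicate 2, with a median log2 ratio of -0.62 over these 6, which were picked for being lower. Of the other loci in these introns of Htr2c and Cdc20b, Mir1912 (-0.75) and Mir449b (-1.47) passed the binomial test, and Mir764 (-0.35, -0.87 to 0.17) and Mir449c (-0.65, -1.39 to 0.07) did not. A candidate explanation is more choroid plexus or ciliated tissue in replicate 1, since Htr2c is abundant in choroid plexus. Its test used Mir204 (2456 CPM, -0.40, -0.43 to -0.37) and Mir211 (4.22 CPM, 0.14, -0.69 to 1.00), taken as the choroid loci of the fixed lists. Their median was -0.13. The rule asked for both intervals on the same side of 0. The interval of Mir204 lay below 0, but Mir211, with 23 and 30 counts, was too sparse for the rule to decide. Tissue content and collection day, with 1 library per collection day, cannot be told apart.

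The medians of the let-7 and Dlk1-Dio3 lists lay above those of matched lists in the ratio of replicate 2 to replicate 1, and those of the Hox and miR-17 lists below, with 0 members called once the common dispersion was allowed for. A trend with the GC content of the whole hairpins over 311 loci could shift any of these 4 lists towards its median by at most 0.0300 log2. This is the upper bootstrap 95% bound over loci, which are not independent. A shift of that size was too small to account for medians of 0.10 to 0.24 and -0.20 to -0.38. The libraries hold RNA under 30 nucleotides, and the GC content of the sequenced strand was not tested, so an effect of it stays open. A candidate explanation for let-7 and miR-17 is that replicate 2 was more advanced in development, but the neuronal list lay at percentile 90.3 and the pluripotency list at 19.015, inside the central 95%, so this stays open. Collection day differs between the libraries too and was not tested.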
